A study of Mus musculus with 24 samples.

How the data were processed

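RNA sequencing measured gene expression in the dentate gyrus, the part of the hippocampal formation that holds the granule cells and adds neurons in adult life. The 24 libraries came from wild-type (WT) mice, APP/PS1 mice without treatment, and APP/PS1 mice given the drug BCI-838, a running wheel, or both. Per the labels, BCI-838 was given by mouth at 5 mg/kg daily for 1 month, and wheel access lasted 1 month. The series design gives 5 mice per group, and 4 libraries of the BCI-838 group were used here. The labels put each library in its group. Replicates are described as separate mice.

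Whole-number read counts per gene were deposited in a table of the whole series, and per the submitters' processing notes the tools were STAR, HTSeq and DESeq with the mouse build mm10. Versions, the read layout and whether counting used strand are not given in the sources used here. A gene and a partner on the opposite strand therefore cannot be separated with certainty. The authors also deposited normalised values as a second signal table. Each of its columns equalled the counts divided by 1 factor per library, between 0.880 and 1.175. Every factor matched a DESeq size factor recomputed from the counts to a relative difference of at most 2.2e-16. The table held 18357 of the 26667 genes, and each of these had a count in at least 21 libraries. It was checked against the counts and not used in a test. No 2 libraries agreed within sampling noise, since the lowest chi-square per gene between any pair was 22.0.

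The deposited counts summed to between 48656360 and 64632882 per library. The filterByExpr function of edgeR, with a minimum count of 10 and a minimum total of 15, kept 18286 genes. Counts were scaled with TMM factors and fitted in 1 model with a mean per group over all 24 libraries. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with robust dispersion estimates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F. Levels are CPM, the counts scaled by library size and TMM factor, with the SD over the libraries of a group. Gene coordinates are from the GRCm38 annotation, the assembly that mm10 names.

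There were 9 comparisons tested gene by gene: APP/PS1 control against WT, each of the 3 treatments against APP/PS1 control, each single treatment against both together, the interaction of drug and wheel, and the drug and the wheel each averaged over the other. A further 3 contrasts set the treated groups against WT. Of 34 gene lists for cell types, tissue neighbours and pathways, 32 had at least 3 measured members to test, and these were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01. Camera was then run again with the correlation estimated from the residuals, and fry tested whether the genes of a list moved 1 way on balance. Benjamini-Hochberg adjustment ran over the 32 lists of each contrast.

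Named genes followed a rule. In each comparison the 10 called genes with the smallest p in each direction were named, leaving out predicted genes without a name of their own. Where fewer than 5 genes passed, all of those and the 3 with the smallest p among the others were named. App and Prnp were always given for the genotype, and Grm2 and Grm3, the targets of the drug, for contrasts with it. Members named for a list are among the 4 with the smallest p, and other genes belong to a library measure or to a test chosen after the results were seen, or are said to have been chosen after their values were seen. Some genes that these rules select are not reported here. The groups, the tests, this rule, the gene lists and most alternatives were fixed before the data were examined.

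The alternatives were DESeq size factors in place of TMM, no filter on low counts, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma voom with quality weights, 1 surrogate variable from sva 3.50.0, the replicate number as a block, a tissue covariate (CA field list minus granule list), fits of the compared libraries alone, and leaving out each library in turn. A further 3 alternatives were chosen after seeing the data. The first leaves out the 4 libraries with over 100 Ttr CPM, which keeps only replicates 1 and 3 of the APP/PS1 controls. The others add the mean log2 CPM of the choroid plexus list or of a list of dorsal midbrain transcription factors as a covariate. The mean log2 CPM of a list used a prior count of 2. A sex covariate was not run, since no library differed from the others in its sex-linked transcripts.

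The fit was tested on simulated counts for the 18286 genes, with each gene's mean over all 24 libraries and the real library sizes. Each gene was drawn on its own, so the shares and false calls below hold for data without variation that genes share. In the genotype simulation 44.8% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 83.3% of those changed 4-fold were called. The shares were 37.3%, 59.7% and 86.4% in the drug simulation and 47.8%, 65.7% and 87.9% in the exercise simulation. For the combined treatment they were 35.8%, 65.7% and 89.4%. For the drug averaged over the wheel they were 56.7%, 79.1% and 97.0%, and for the wheel averaged over the drug 55.2%, 71.6% and 93.9%. Of 18032 unchanged genes, 3 to 12 were called per simulation, with 12 for the drug averaged over the wheel. Camera at the preset correlation also called 2 lists that had not been shifted in the drug averaged simulation, and 0 in the other simulations.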

Results

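Expression was profiled in the dentate gyrus of WT mice and of APP/PS1 mice, a transgenic model that forms amyloid plaques. The drug under study, BCI-838, is the oral pro-drug of an antagonist of the metabotropic glutamate receptors mGluR2 and mGluR3, encoded by Grm2 and Grm3. The series asks how this drug and voluntary running, alone and together, act on adult neurogenesis and behaviour in such mice. The libraries were 5 from WT controls, 5 from APP/PS1 controls, 4 from APP/PS1 mice on BCI-838, 5 from APP/PS1 mice with a running wheel and 5 from APP/PS1 mice with both. Total counts ranged from 48656360 to 64632882 per library.

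The first comparison asked what the transgenes change in untreated mice. Prnp and App were higher in APP/PS1 controls than in WT. Prnp, which encodes the prion protein and lies at chromosome 2 from 131909928 to 131938429, rose 2.37-fold, from 846 ± 98.7 CPM (SD, n = 5) to 2006 ± 173 CPM (SD, n = 5). App, which encodes the amyloid precursor protein and lies at chromosome 16 from 84949685 to 85173766, rose 1.96-fold, from 1728 ± 248 CPM (SD, n = 5) to 3379 ± 371 CPM (SD, n = 5). All 5 APP/PS1 control libraries lay above every WT library for both genes.

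Prnp had a log2 fold change of 1.25 (SE 0.10, adjusted p = 1.33e-07) and App one of 0.97 (SE 0.12, adjusted p = 0.000189) by the quasi-likelihood test of edgeR. They were the only 2 of 18286 genes called, with 504 genes at an unadjusted p under 0.05. DESeq2 called 14 genes and voom 2. The transgene-related list was called with the preset correlation (adjusted p = 1.08e-41) and kept its call with an estimated one (adjusted p = 5.15e-08 with an estimated correlation). Both genes were also raised over WT in every treated group. App was 2.05-fold higher with the drug, 1.86-fold higher with the wheel and 2.24-fold higher with both, and Prnp was 2.34-fold, 2.37-fold and 2.58-fold higher. With the compared libraries alone App lost its call for the wheel against WT (adjusted p = 0.20). Prnp shares exonic sequence on its strand with Prn, and App with a predicted gene on the other strand, so their counts may include reads of these partners. Counts of App and Prnp also cannot separate the native genes from reads of the transgenes, so a rise of the native genes was not shown. Fitted with the compared libraries alone, App had an adjusted p of 0.0622, which left 1 call, and without APP/PS1 control replicate 1 the count was 3.

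**Figure D1:**
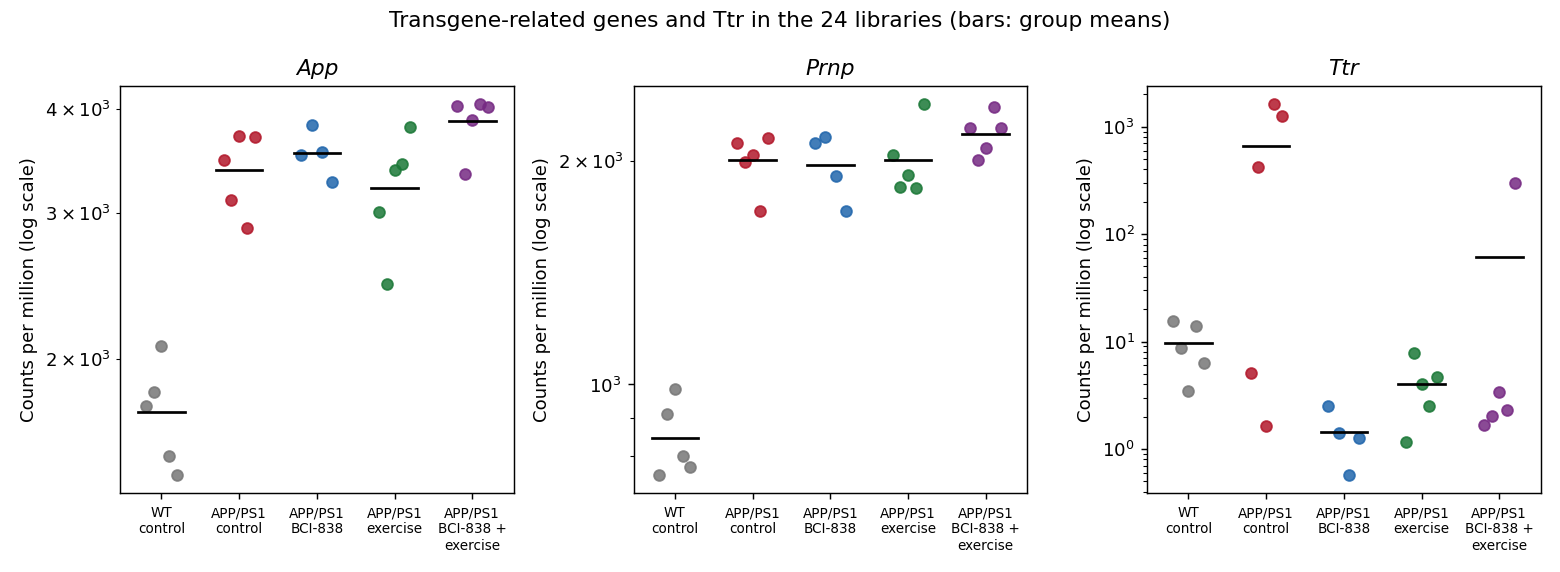
Levels in CPM, on a log axis, of App, Prnp and Ttr in each of the 24 libraries (points) with group means (bars), by group. App and Prnp lie above all WT libraries in the APP/PS1 controls, while Ttr stands between 297 and 1615 CPM in 4 libraries and at or under 15.6 CPM in the other 20.

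Next by p in this comparison were Sulf1, which edits heparan sulfate outside the cell, at 14.5 ± 7.51 CPM (SD, n = 5) against 5.12 ± 1.64 CPM (SD, n = 5) in WT (2.82-fold, adjusted p = 0.146 by edgeR), Mia1 (5.37-fold, log2 fold change 2.43, adjusted p = 0.772) and the water channel Aqp1 (7.01-fold, log2 fold change 2.81, adjusted p = 0.772). None of these 3 passed by edgeR, while DESeq2 called all of them. For Sulf1, DESeq2 gave an adjusted p of 0.000443, the lowest of the alternatives; its log2 fold change was 0.74 (adjusted p = 0.981) without 4 libraries with high Ttr and 0.93 (1.00, the highest) with the choroid plexus covariate. The log2 fold change of Mia1 was 0.71 and 1.01 in these fits. Aqp1 belongs to the choroid plexus and ependyma list, of which 21 of 21 members were higher, with a median log2 fold change of 2.46 and 18 members passing when adjusted over the list alone. That list was called with the preset correlation (adjusted p = 2.59e-28) and missed the threshold otherwise (adjusted p = 0.0530 with an estimated correlation). Ttr, the most abundant choroid plexus transcript, reached 425 CPM in APP/PS1 control replicate 2, 1615 CPM in replicate 4 and 1269 CPM in replicate 5, and 297 CPM in replicate 5 of the combined group. Without these 4 libraries the choroid list turned lower (adjusted p = 0.0399) and Aqp1 had a log2 fold change of -0.20.

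Genes of the glial response to plaques did not pass singly. Of 54 plaque-induced genes 37 were higher, with a median log2 fold change of 0.05, and Lyz2 was at 0.41 (SE 0.18) and Cd63 at 0.25 (SE 0.13). The list was called with the preset correlation (adjusted p = 0.0107), but not otherwise (adjusted p = 0.744 with an estimated correlation), nor without WT replicate 2 (0.131), WT replicate 5 (0.0804) or APP/PS1 control replicate 1 (0.660). The disease-associated microglia list had 11 members higher and 12 lower (adjusted p = 0.654, and 0.744 with an estimated correlation), with a median of -0.03 against a mean of 0.10. Of 54 cytosolic ribosomal protein genes 53 were higher, by a median of 0.07 (adjusted p = 9.70e-06, and 0.744 with an estimated correlation). Of 15 GABA receptor genes 13 were lower, among them Gabrb2 at -0.31 (SE 0.14) and Gabrd at -0.29 (SE 0.21). The GABA receptor list had an adjusted p of 0.00714, or 0.255 with an estimated correlation, and 0.10 at the preset one without WT replicate 2.

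The second comparison asked what BCI-838 changes in sedentary APP/PS1 mice. No gene passed by edgeR, with 1863 genes at an unadjusted p under 0.05. The smallest p values belonged to genes lower with the drug in all 4 libraries than in any of the 5 controls. Fam160a1 was 3.86-fold lower (log2 fold change -1.95, SE 0.36). Hrk, which encodes a pro-apoptotic BH3-only protein, was at 24.9 against 75.7 CPM (-1.61, SE 0.30). Wnt9a, a secreted Wnt ligand at chromosome 11 from 59306928 to 59333552, was at 4.00 ± 0.944 CPM (SD, n = 4) against 16.8 ± 4.97 CPM (SD, n = 5) (-2.07, SE 0.40). All 3 had an adjusted p of 0.148, and DESeq2 and voom called them. The targets of the drug did not pass either. Grm2, at chromosome 9 from 106643095 to 106656082, had a log2 fold change of -0.47 (SE 0.32, adjusted p = 0.643), and Grm3, at chromosome 5 from 9485541 to 9725170, one of 0.21 (SE 0.18, adjusted p = 0.730). Without the 4 high-Ttr libraries Grm2 was at -0.033 and Grm3 at -0.18. The controls then were replicates 1 and 3 alone, with the lowest granule scores (6.07 and 5.07) of that group. They also had its lowest Grm2 (100.2 and 75.4 CPM) and highest Grm3 (41.9 and 67.0 CPM). A value that moves in this fit therefore cannot be put down to choroid plexus tissue alone.

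Among the lists, 53 of 54 ribosomal protein genes were lower with the drug, by a median log2 fold change of -0.10 (adjusted p = 3.84e-06, and 0.887 with an estimated correlation). Rps2 was at -0.28 (SE 0.10) and Rplp0 at -0.19 (SE 0.09). Of 15 astrocyte genes 14 were higher, among them the growth factor receptor Fgfr3 at 0.45 (SE 0.13), the 1 member that passed when adjusted over the list alone. The astrocyte list had an adjusted p of 0.00110, or 0.872 with an estimated correlation, and its call was lost at the preset one without the 4 choroid plexus libraries (0.599) and with the dorsal midbrain covariate (0.0587). Of 21 choroid plexus genes 20 were lower, by a median of -4.14 (adjusted p = 3.78e-17, and 0.541 with an estimated correlation); 3 of the 4 high-Ttr libraries are APP/PS1 controls. Without those 4 libraries it was not called (0.274). The neuroblast list had 13 of 22 members higher (median 0.08, adjusted p = 0.351, and 0.887 with an estimated correlation), and the stem and progenitor list 10 of 20 (median 0.03, adjusted p = 0.918, and 0.952 with an estimated correlation). The list of metabotropic glutamate receptors and Gi signalling had a median of 0.07 and a mean of -0.01, with 12 of 23 members higher (adjusted p = 0.682, and 0.928 with an estimated correlation). In all 4 libraries of this group the dorsal midbrain factor Pax7, a gene chosen after its values were seen, stood between 6.82 and 14.0 CPM, and it ranged from 0 to 16.4 CPM in the others.

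DESeq2 called 170 genes and voom with quality weights 425 genes for the drug, against 0 by edgeR. The edgeR count was 9 with the compared libraries alone and 12 without APP/PS1 control replicate 1.

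The third comparison set APP/PS1 mice with a wheel against APP/PS1 controls. Sulf1, at chromosome 1 from 12692277 to 12861192, was the 1 gene called. It fell to 4.03 ± 0.952 CPM (SD, n = 5) from 14.5 ± 7.51 CPM (SD, n = 5), a log2 fold change of -1.84 (SE 0.29, adjusted p = 0.0292 by edgeR), and lay below every control in all 5 libraries. Next were the choline transporter Slc5a7 (-3.33, adjusted p = 0.252), Mlf1 (-3.34, adjusted p = 0.252) and Dnaic2 (-1.11, adjusted p = 0.252), a component of motile cilia, and these 3 did not pass by edgeR, while DESeq2 called them. Without the 4 high-Ttr libraries Slc5a7 was at -0.70 and Mlf1 at -1.67, and with the choroid plexus covariate they were at -1.54 and -1.60. The unadjusted count was 995, and DESeq2 called 61 genes and voom 0.

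The call of Sulf1 was lost in several other fits. Without the 4 high-Ttr libraries its log2 fold change was -1.09 (adjusted p = 0.883), and with the choroid plexus covariate it was -1.12 (adjusted p = 1.00). The call was also lost in the fits with the replicate number as a block (adjusted p = 0.0526), with a surrogate variable (0.0559), with voom (0.150) and with the compared libraries alone (0.843). Leaving out 1 library ended it for APP/PS1 control replicates 4 (0.0808) and 5 (0.0628) and for exercise replicates 1 (0.203), 2 (0.144), 3 (0.122) and 5 (0.212), each with a count of 0 genes. The count was 27 without APP/PS1 control replicate 1 and 5 without replicate 3.

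Genes of protein synthesis and of the respiratory chain were higher with the wheel as groups, while no member passed singly. All 54 ribosomal protein genes were higher, by a median log2 fold change of 0.16, among them Rps26 at 0.25 (SE 0.08) and Rpl28 at 0.24 (SE 0.10). Their adjusted p was 1.41e-17, or 0.760 with an estimated correlation. Of 51 nuclear-encoded respiratory chain genes 48 were higher, by a median of 0.14, among them Ndufs3 at 0.17 (SE 0.07) and Ndufs7 at 0.20 (SE 0.08) (adjusted p = 1.82e-13, and 0.760 with an estimated correlation). The ribosomal protein score was above that of every control in 3 of 5 exercise libraries, but not in replicates 3 (7.38) and 4 (7.23), with controls between 7.27 and 7.56. Reads on the rRNA-like loci Lars2 and Mir5105 took 0.203% ± 0.0298 (SD, n = 5) of counts with the wheel against 0.310% ± 0.0661 (SD, n = 5) in controls, lower in all 5 libraries than in any control. Of 16 endothelial genes 15 were higher, by a median of 0.25, and 4 passed when adjusted over the list alone. Slco1a4, a transporter of the blood-brain barrier, was at 0.43 (SE 0.11) and Ly6c1 at 0.42 (SE 0.13). The endothelial list had an adjusted p of 1.22e-09, or 0.139 with an estimated correlation. Of 24 heat shock and unfolded protein genes 18 were lower, among them the endoplasmic reticulum chaperones Hspa5 at -0.30 (SE 0.10) and Hsp90b1 at -0.24 (SE 0.09) (adjusted p = 0.00166, and 0.779 with an estimated correlation). Without APP/PS1 control replicate 1 the preset p of that list was 0.196. All 21 choroid plexus genes were lower (median -4.12, adjusted p = 7.76e-31, and 0.0788 with an estimated correlation), but the list was not called without the 4 high-Ttr libraries (0.676). The neuroblast list had 11 of 22 members higher, with a median of 0.00 and a mean of -0.20 (adjusted p = 0.668, and 0.946 with an estimated correlation).

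The fourth comparison set both treatments together against APP/PS1 controls. No gene passed by edgeR, with 1938 genes at an unadjusted p under 0.05, while DESeq2 called 82 and voom 0. Sulf1 (log2 fold change -1.68, SE 0.28, adjusted p = 0.0995), the growth factor Bmp7 (-1.35, SE 0.25, adjusted p = 0.142) and Wfikkn2 (-3.25, SE 0.65, adjusted p = 0.229) had the smallest p values. For Sulf1 the adjusted p ran from 3.01e-05 with DESeq2 to 0.637 with the choroid plexus covariate (log2 fold change -1.01), and without the 4 high-Ttr libraries its log2 fold change was -0.94 (0.408). Wfikkn2 was at -1.46 without those libraries and at -1.47 with that covariate. DESeq2 called all 3. Grm2 was at -0.48 (SE 0.30, adjusted p = 0.585) and Grm3 at 0.01 (SE 0.17, adjusted p = 0.991), or at 0.15 and -0.41 without the 4 libraries. The count was 17 without combined replicate 2 and 1 without APP/PS1 control replicate 1.

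Homeostatic microglia genes were higher in the combined group in 15 of 17 cases, by a median log2 fold change of 0.20, among them the purinergic receptor gene P2ry12 at 0.28 (SE 0.11) and Fcrls at 0.32 (SE 0.13). The list had an adjusted p of 0.000205, or 0.326 with an estimated correlation, and 0.232 at the preset one without the 4 high-Ttr libraries. Of 29 genes for ionotropic glutamate receptors and the postsynaptic density 24 were higher, by a median of 0.22 (adjusted p = 1.64e-05, and 0.326 with an estimated correlation). The adhesion gene Nlgn1 was at 0.38 (SE 0.13), the scaffold gene Shank2 at 0.35 (SE 0.12) and the NMDA receptor subunit gene Grin2b at 0.64 (SE 0.24). All 54 ribosomal protein genes were lower, by a median of -0.10 (adjusted p = 1.21e-05, and 0.701 with an estimated correlation), among them Rpsa at -0.20 (SE 0.10) and Rpl8 at -0.16 (SE 0.08). Of 16 mural cell and fibroblast genes 13 were lower (median -0.37, adjusted p = 0.000517, and 0.326 with an estimated correlation), with Igf2 at -1.44 (SE 0.37) and Lum at -1.40 (SE 0.38). Of 17 markers of thalamus and cortex 14 were lower (median -0.52, adjusted p = 0.00421, and 0.326 with an estimated correlation), among them Zic1 at -2.93 (SE 0.82) and Calb2 at -2.11 (SE 0.83). The choroid plexus list had 21 of 21 members lower (median -2.53, adjusted p = 6.19e-14, and 0.326 with an estimated correlation), and was not called without the 4 high-Ttr libraries (0.268).

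**Figure D2:**
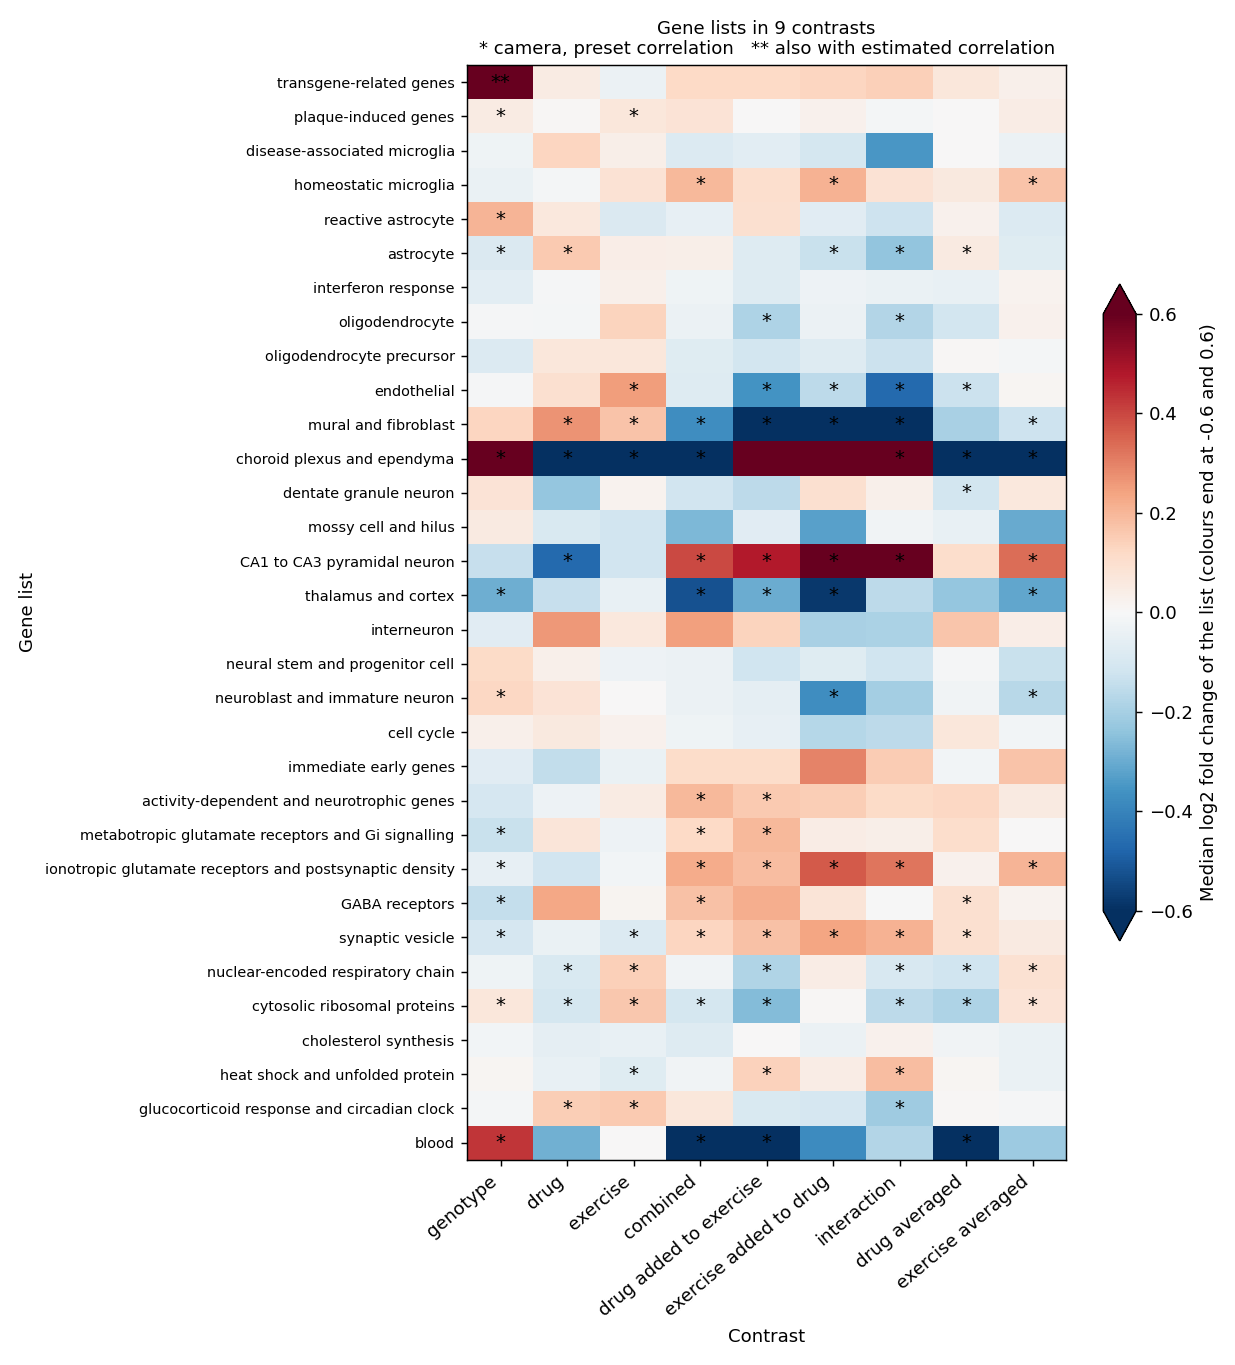
Median log2 fold change (colour, ending at -0.6 and 0.6) of the 32 gene lists in the 9 gene-wise contrasts, with 1 asterisk for a camera call at the preset correlation and 2 asterisks for a call that also holds with an estimated correlation. Only the transgene-related list in the genotype contrast carries 2 asterisks.

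Adding the drug to the wheel was tested within running mice. No single gene passed by edgeR. Dpy19l3 (log2 fold change 0.77, SE 0.13), the adaptor gene Card10 (-0.79, SE 0.14) and Pclo (0.72, SE 0.14), which encodes the presynaptic scaffold piccolo, had the smallest p values, each with an adjusted p of 0.0856; DESeq2 and voom called them. Pclo was higher in all 5 combined libraries than in any exercise library, at 442.0 against 269 CPM. Grm2 was at -0.44 (SE 0.30, adjusted p = 0.448) and Grm3 at -0.01 (SE 0.17, adjusted p = 0.977), or at -0.25 and -0.040 without the 4 high-Ttr libraries. Of 25 synaptic vesicle genes 20 were higher, by a median of 0.18, and 4 passed when adjusted over the list alone; the active zone gene Bsn was at 0.61 (SE 0.15). This list had an adjusted p of 2.52e-05, or 0.337 with an estimated correlation. Of 29 ionotropic receptor and postsynaptic genes 23 were higher (median 0.18, adjusted p = 0.000205, and 0.417 with an estimated correlation), among them Grin2b at 0.88 (SE 0.24) and Shank2 at 0.43 (SE 0.12).

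Lower in the same comparison were all 54 ribosomal protein genes, by a median of -0.26, with 0 passing over all genes and 44 adjusted over the list alone. Rps26 was at -0.38 (SE 0.08) and Rpsa at -0.41 (SE 0.10), and the list had an adjusted p of 1.30e-23, or 0.417 with an estimated correlation. The ribosomal score was above all combined libraries (7.21 to 7.45) in exercise replicates 1 (7.79), 2 (7.78) and 5 (7.64). Exercise replicates 3 (7.38) and 4 (7.23) lay inside that range. Reads on Lars2 and Mir5105 took a mean of 0.203% of counts with the wheel and 0.288% with both treatments. Of 51 respiratory chain genes 49 were lower (median -0.18, adjusted p = 4.51e-08, and 0.519 with an estimated correlation), with Ndufs7 at -0.30 (SE 0.08) and Ndufs8 at -0.26 (SE 0.08). All 16 endothelial genes were lower, by a median of -0.36, with Itm2a at -0.38 (SE 0.11) and Eng at -0.48 (SE 0.15) and 10 passing over the list alone (adjusted p = 8.57e-08, and 0.337 with an estimated correlation). All 16 mural cell and fibroblast genes were lower, by a median of -0.60, with the smooth muscle actin gene Acta2 at -1.74 (SE 0.41) and Vtn at -0.56 (SE 0.15) and 7 passing over the list alone (adjusted p = 1.16e-06, and 0.337 with an estimated correlation). The unadjusted count was 3210 genes, and DESeq2 called 364 and voom 989. By edgeR the count was 35 with a surrogate variable and 1 with the tissue covariate. It was 400 without exercise replicate 3, 10 without exercise replicate 4, 83 without combined replicate 2 and 3 without combined replicate 4.

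Adding the wheel to the drug was tested within drug-treated mice. Again no gene passed by edgeR. Adra1d, the alpha-1D adrenergic receptor gene, was 2.79-fold higher (log2 fold change 1.48, SE 0.26, adjusted p = 0.122). Lor (0.65, SE 0.12, adjusted p = 0.122) and Rgnef (1.03, SE 0.20, adjusted p = 0.164) followed, and all 3 lay above every drug library in all 5 combined libraries and were called by DESeq2 and voom. Their highest adjusted p came with the dorsal midbrain covariate, where none was called. The mean midbrain score was 2.66 with the drug and -2.09 with both. Grm2 was at -0.01 (SE 0.32, adjusted p = 0.996) and Grm3 at -0.20 (SE 0.18, adjusted p = 0.669), or at 0.18 and -0.23 without the 4 high-Ttr libraries. Of 23 CA1 to CA3 pyramidal neuron genes 21 were higher, by a median of 0.81, among them Hs3st4 at 1.35 (SE 0.35) and Rgs14, a marker of CA2, at 1.67 (SE 0.44), with 6 passing over the list alone. The list had an adjusted p of 1.44e-07, or 0.244 with an estimated correlation. Of 29 ionotropic receptor and postsynaptic genes 22 were higher (median 0.37, adjusted p = 1.44e-07, and 0.244 with an estimated correlation). Adjusted over the list alone, 16 passed as higher and 1 as lower, with Cacng8 at 0.89 (SE 0.25) and Camk2a at 0.82 (SE 0.23). All 16 mural cell and fibroblast genes were lower (median -0.75, adjusted p = 1.44e-07, and 0.244 with an estimated correlation), among them the collagen gene Col1a2 at -1.58 (SE 0.42). Of 17 homeostatic microglia genes 15 were higher, with Cx3cr1 at 0.31 (SE 0.11) (adjusted p = 0.000402, and 0.533 with an estimated correlation), but the list lost its call with the dorsal midbrain covariate (0.638). Pax7 stood at 0 to 3.93 CPM in the combined group against 6.82 to 14.0 CPM with the drug alone. The unadjusted count was 2619 genes, DESeq2 called 256 and voom 876, and edgeR called 111 with the compared libraries alone and 2 without combined replicate 3.

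The interaction asked whether the drug acted differently in running and sedentary mice. No gene passed by edgeR, with 1756 genes at an unadjusted p under 0.05, while DESeq2 called 77 and voom 0. The choroid plexus gene Ttr (log2 difference 12.8, SE 2.58), Calml4 (8.55, SE 1.71) and the predicted gene 2310007L24Rik (10.1, SE 2.10) had the smallest p values, each with an adjusted p of 0.272. Calml4 had a mean of only 0.0212 CPM with the drug. That of 2310007L24Rik was 0.00427 CPM with the drug and 0.00361 CPM with the wheel. These levels are near the floor, so the sizes of both differences are uncertain. Without combined replicate 5 the values of Ttr and Calml4 were 8.08 and 6.90, and without the 4 high-Ttr libraries 0.43 and 4.18, while that of 2310007L24Rik was then 5.05. DESeq2 called all 3. Grm2 was at 0.03 (SE 0.44, adjusted p = 0.988) and Grm3 at -0.22 (SE 0.25, adjusted p = 0.817), or at -0.22 and 0.14 without the 4 high-Ttr libraries. All 23 pyramidal neuron genes had a positive difference, by a median of 1.04 (adjusted p = 4.42e-07, and 0.185 with an estimated correlation), among them Hs3st4 at 1.77 (SE 0.47) and Neurod6 at 1.69 (SE 0.51). The dorsal midbrain score, a mean log2 CPM, differed between the same groups, at 0.12 ± 2.00 (SD, n = 5) in APP/PS1 controls, 2.66 ± 0.48 (SD, n = 4) with the drug, 0.09 ± 2.61 (SD, n = 5) with the wheel and -2.09 ± 2.75 (SD, n = 5) with both. The pyramidal list kept its preset call with that score as a covariate. Negative differences were found for 15 of 16 endothelial genes (median -0.47, adjusted p = 6.34e-09, and 0.185 with an estimated correlation), with Itm2a at -0.62 (SE 0.15) and Slco1a4 at -0.58 (SE 0.16). The same held for 15 of 16 mural cell and fibroblast genes (median -0.81, adjusted p = 3.75e-09, and 0.185 with an estimated correlation), with Myh11 at -2.16 (SE 0.51) and Acta2 at -2.41 (SE 0.59).

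Averaged over sedentary and running mice, BCI-838 raised 27 genes and lowered 28. Penk, which encodes the precursor of the enkephalin opioid peptides and lies at chromosome 4 from 4133531 to 4138819, rose 4.37-fold (log2 fold change 2.13, SE 0.35, adjusted p = 0.0259 by edgeR). Its level was 23.8 ± 6.92 CPM (SD, n = 5) in APP/PS1 controls and 26.3 ± 4.45 CPM (SD, n = 5) with the wheel, against 143 ± 94.6 CPM (SD, n = 4) with the drug and 83.5 ± 75.8 CPM (SD, n = 5) with both. Of the 9 drug libraries 7 lay above all 10 libraries without the drug. Wnt9a fell by 1.57 on the log2 scale (SE 0.26, adjusted p = 0.0259), and 8 of the 9 drug libraries lay below all others. Calb1, the member of the granule neuron list with the smallest p, encodes calbindin, a calcium-binding protein of mature granule cells, and lies at chromosome 4 from 15881264 to 15908064. It fell by 1.18 (SE 0.25, adjusted p = 0.0419), from 102 ± 40.8 CPM (SD, n = 5) to 39.1 ± 10.4 CPM (SD, n = 4) in sedentary mice, and stood at 105 ± 24.9 CPM (SD, n = 5) against 53.3 ± 30.1 CPM (SD, n = 5) in running mice. Penk shares exonic sequence with a gene on the opposite strand.

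**Figure D3:**
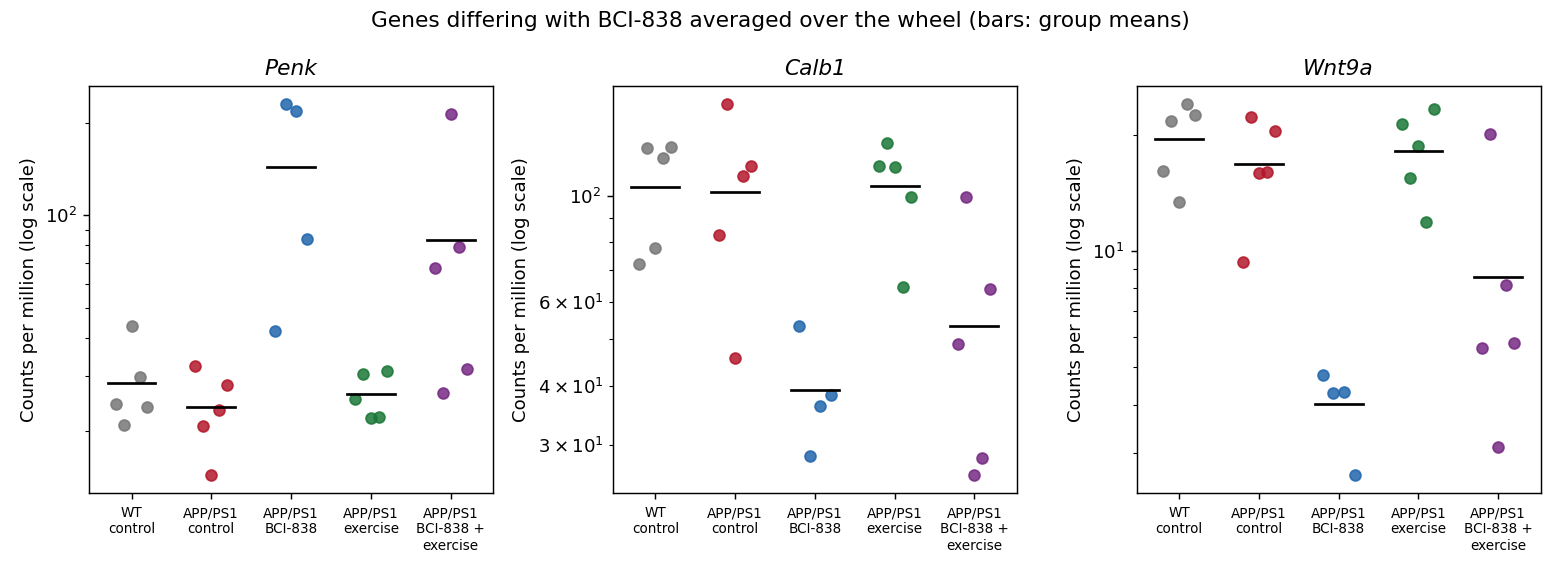
Levels in CPM, on a log axis, of Penk, Calb1 and Wnt9a in each library (points) with group means (bars), by group. Penk is at most 43.6 CPM in every library without the drug, and reaches 230 CPM with the drug alone and 213 CPM with both treatments.

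Other genes raised by the drug were the diacylglycerol kinase gene Dgkb (log2 fold change 0.73), the small GTPase gene Rab8b (0.52), Parp8 (0.50), Dpy19l3 (0.55), Rassf8 (0.92), Cass4 (0.88), the AMP kinase subunit gene Prkab2 (0.47), the Ras activator gene Sos1 (0.28) and Dopey2 (0.27). Lowered genes were Fam160a1 (-1.33), Ccdc63 (-1.48), Plekhh3 (-0.47), the interleukin receptor gene Il11ra1 (-0.46), the mitochondrial iron carrier gene Slc25a28 (-0.25), Fance of the Fanconi anaemia complex (-0.32), Tmem109 (-0.30) and the spliceosome gene Snrpb (-0.28). Slc25a28 was lower in all 9 drug libraries than in any of the 10 others. Adjusted p values of all these genes were between 0.0259 and 0.0329. Exons of Fam160a1, Plekhh3, Il11ra1, Ccdc63, Cass4, Prkab2 and Fance overlap those of other genes, so reads may be shared. Oprd1, the delta opioid receptor gene, at 0.78 (SE 0.16, adjusted p = 0.0409), and Oxtr, the oxytocin receptor gene, at 1.02 (SE 0.22, adjusted p = 0.0427), were also raised, and are named here after their values were seen. Grm2 was at -0.46 (SE 0.22, adjusted p = 0.278) and Grm3 at 0.10 (SE 0.13, adjusted p = 0.724). Voom with quality weights called Grm2 (-0.60, adjusted p = 0.0498), and its adjusted p was at most 0.811 over the alternatives, without the 4 high-Ttr libraries (-0.14), where Grm3 was at -0.11.

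As groups, all 54 ribosomal protein genes were lower with the drug, by a median log2 fold change of -0.19, with 45 passing when adjusted over the list alone and 0 over all genes. Rps26 was at -0.24 (SE 0.06) and Rpsa at -0.29 (SE 0.07), and the list had an adjusted p of 1.15e-22, or 0.726 with an estimated correlation. The libraries without the drug include exercise replicates 1, 2 and 5, whose ribosomal scores (7.79, 7.78 and 7.64) were the highest of all. A fit without all of these was not run. The sedentary drug contrast, in which the list was also lower, does not hold them. Of 51 respiratory chain genes 48 were lower (median -0.12, adjusted p = 1.33e-07, and 0.726 with an estimated correlation), with Ndufs7 at -0.20 (SE 0.06) and Ndufb2 at -0.24 (SE 0.07). All 8 blood genes were lower, by a median of -0.60 (adjusted p = 0.00426, and 0.726 with an estimated correlation), among them the haemoglobin genes Hba-a1 at -0.72 (SE 0.20) and Beta-s at -1.03 (SE 0.34). Of 20 granule neuron genes 14 were lower, by a median of -0.11, and 3 passed over the list alone: Calb1, Tdo2 at -1.92 (SE 0.46) and Dsp at -1.66 (SE 0.53). The granule list had an adjusted p of 0.0184, or 0.818 with an estimated correlation. Its direction turned with the tissue covariate (0.768), but that covariate holds the score of this same list, so the turn says little. It also turned without the 4 high-Ttr libraries (0.397). Its call was lost without APP/PS1 control replicates 2 (0.0856) and 5 (0.0539), exercise replicate 3 (0.0687) and combined replicates 4 (0.0772) and 5 (0.102).

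The unadjusted count for the averaged drug effect was 3285 genes, and DESeq2 called 608 and voom 2162. The count of 55 was sensitive to single libraries. It was 0 without drug replicate 2 or 3, exercise replicate 1 or combined replicate 1, 6 without drug replicate 4, 7 without APP/PS1 control replicate 2, 11 without exercise replicate 2 or combined replicate 3, and 13 without APP/PS1 control replicate 5. Penk and Wnt9a lost their calls wherever the count was 0, and Wnt9a also without drug replicate 4 (adjusted p = 0.0602). Sos1, Dgkb, Dopey2, Rassf8, Cass4, Ccdc63, Prkab2 and Rab8b lost theirs in more of these fits than Penk or Wnt9a. By edgeR with the compared libraries alone Sos1 (adjusted p = 0.061) and Dgkb, Dopey2, Rassf8, Cass4 and Ccdc63 (0.059 for each) also lost their calls. The count was 16 without APP/PS1 control replicate 1, 17 without exercise replicate 5, 23 without APP/PS1 control replicate 4, and 31 without combined replicate 4. It was 96 without combined replicate 5, 287 without combined replicate 2, 309 without APP/PS1 control replicate 3, 364 without exercise replicate 3 and 883 without exercise replicate 4. Without the 4 high-Ttr libraries and with the choroid plexus covariate no gene passed, at a smallest adjusted p of 0.0890 and 0.0852.

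Averaged over the drug, the wheel changed no single gene by edgeR. Lor (log2 fold change 0.46, SE 0.08, adjusted p = 0.134), Sulf1 (-1.12, SE 0.20, adjusted p = 0.135) and Plbd1 (-1.48, SE 0.30, adjusted p = 0.284) had the smallest p values. For Sulf1 the adjusted p ran from 0.000456 with DESeq2 to 1.00 with the dorsal midbrain covariate, and without the 4 high-Ttr libraries its log2 fold change was -0.75 (0.334). DESeq2 called all 3 and voom called Lor. Of 17 homeostatic microglia genes 15 were higher, by a median of 0.17, among them Tmem119 at 0.24 (SE 0.08) and P2ry12 at 0.19 (SE 0.08). That list had an adjusted p of 3.53e-05, or 0.660 with an estimated correlation, and lost its call with the dorsal midbrain covariate (0.0995). Of 29 ionotropic receptor and postsynaptic genes 22 were higher (median 0.20, adjusted p = 3.37e-05, and 0.660 with an estimated correlation), with Grik5 at 0.28 (SE 0.09) and Camk2a at 0.44 (SE 0.16). Respiratory chain genes were higher in 49 of 51 cases (median 0.09, adjusted p = 1.25e-07, and 0.686 with an estimated correlation) and ribosomal protein genes in 54 of 54 (median 0.08, adjusted p = 1.24e-06, and 0.899 with an estimated correlation). Ndufa5 was at 0.26 (SE 0.09), Ndufs3 at 0.14 (SE 0.05), Rps2 at 0.19 (SE 0.07) and Rplp2 at 0.17 (SE 0.07). The stem and progenitor list had 15 of 20 members lower (median -0.13, adjusted p = 0.250, and 0.663 with an estimated correlation). The unadjusted count was 1827 genes, DESeq2 called 7 and voom 1, and edgeR called 1 without APP/PS1 control replicate 1 or 5.

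Whether a treatment turned back the difference between APP/PS1 and WT was asked with the log2 fold changes of all 18286 genes. The genotype and each treatment share the APP/PS1 controls, which alone gives a negative relation. Across genes, which are not independent replicates, r was -0.51 for the drug, -0.54 for the wheel and -0.54 for both, against -0.47, -0.50 and -0.50 in simulations with unchanged groups. The covariances were -0.0614, -0.0535 and -0.0607, against simulated values of -0.0432, -0.0435 and -0.0433. Without the 4 high-Ttr libraries r was -0.55, -0.67 and -0.69, against simulated values of -0.685, -0.71 and -0.69. The covariances were then -0.0820, -0.0972 and -0.125, against -0.107, -0.107 and -0.108, so the drug and the wheel lay nearer to 0 than the simulations. With the controls split between the 2 comparisons, the mean covariance over 20 splits was -0.0110 for the drug (range -0.0493 to 0.0795), -0.00316 for the wheel (-0.0298 to 0.0644) and -0.0104 for both (-0.0467 to 0.0435). Each range spans 0. In 20 simulations this mean ranged from -0.00267 to 0.00317 for the drug, from -0.00322 to 0.00345 for the wheel and from -0.00195 to 0.00319 for both. The observed means of the drug and of both treatments lay below these ranges, and that of the wheel lay inside. The simulations drew each gene on its own, without the variation that genes share among the real libraries. Their ranges may therefore be too narrow, and a mean outside them does not show that a treatment turned back the genotype difference. With a filter of 1 CPM in 5 libraries the means were -0.000197 for the drug, 0.0064 for the wheel and -0.00342 for both. The simulations were not repeated with that filter. By the ranges above the drug would lie inside, the wheel above and both treatments below. Only App and Prnp were called for the genotype, so the relation could not be restricted to called genes.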

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

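The tests of choroid plexus tissue, of the genotype, of reads from ribosomal RNA and of fewer granule cells were chosen after the results were seen, the last with more than 1 bound tried, while the splits of the libraries, the matched lists and the tissue covariate were planned.

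For each comparison, 100 splits of the same libraries into groups of the same sizes were counted, the real one included. For the genotype 6 splits gave as many as the real 2 genes and the highest other gave 883, so chance cannot be excluded for a count of 2, whichever genes it holds. App and Prnp themselves lay above all 5 WT libraries in all 19 APP/PS1 libraries, with adjusted p values of 0.000189 and 1.33e-07. For the wheel 4 splits gave as many as the real 1 gene, under the planned share, but the highest other gave 887. Splits that call several times the real count point to a structure among the libraries. With 0 genes called, every split gives as many whatever the data, so the 100 of 100 says nothing on chance for the drug (highest other 42), the combined treatment (286), the drug added to the wheel (559), the wheel added to the drug (10), the interaction (11) and the wheel averaged over the drug (0). For the drug averaged over the wheel the real split alone gave 55, that is 1 of 100, and the highest other gave 6. This lies under the planned share. It is the lowest share that 100 splits can give, and no adjustment was made for the 9 comparisons tested so. The count also fell to 0 without drug replicate 2 or 3, exercise replicate 1 or combined replicate 1. Chance is therefore not excluded.

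Choroid plexus genes were higher in APP/PS1 controls than in WT. Of all 19 APP/PS1 libraries, treated ones included, 4 had more Ttr than the highest WT library and 15 did not. Among the untreated controls, replicates 2 (425 CPM), 4 (1615 CPM) and 5 (1269 CPM) lay above it. Control replicates 1 (5.05 CPM) and 3 (1.62 CPM) did not, which argues against a rise in every untreated APP/PS1 mouse. Since most of the 19 were treated, their count cannot exclude a genotype effect that treatment takes back. Choroid plexus tissue in some dissections may be the source. Over the 4 libraries the log2 ratios of 14 choroid genes to Ttr had a median SD of 0.335 (range 0.0251 to 1.05). The ratio was thus nearly fixed for many of these genes, but not for all. Ttr stood between 297 and 1615 CPM in the 4 libraries and at or under 15.6 CPM elsewhere.

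Ribosomal protein and respiratory chain genes were higher with the wheel (adjusted p = 0.760 for both with an estimated correlation), with a ribosomal score above all controls in 3 of 5 libraries, but not in replicates 3 (7.38) and 4 (7.23). Both medians lay at percentile 100 of 1000 random lists matched on gene length and expression level. The matched genes were drawn singly, so their lists lack the variation that ribosomal or respiratory genes may share between libraries. Their spread may thus be too narrow, and the percentile cannot exclude a bias by length or expression as the whole cause. The ribosomal median was 0.16 against a matched median of 0.08, and the respiratory one 0.14 against 0.07. The matched lists thus rose as well, so such a bias may hold a part of the rise. A shift in reads from ribosomal RNA between libraries cannot be told apart, since its measures differed. The share of counts on Rn45s overlapped, at 0.8764% to 1.498% with the wheel and 0.8601% to 2.42% in controls. Its relation to the ribosomal score was not tested. The share on Lars2 and Mir5105 was lower in all 5 exercise libraries (0.167% to 0.230%) than in any control (0.259% to 0.406%). Over 24 libraries the ribosomal score had r = -0.329 with that share (permutation p = 0.12; rho = -0.148, permutation p = 0.49), and this was the 1 relation tested. Without the 2 farthest libraries r was -0.0350, so the pooled value rests on those, and within groups it was 0.0149, which does not address the difference between the groups.

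In the genes called for the drug averaged over the wheel, choroid plexus tissue as the whole cause is argued against by the median size alone. Without the 4 libraries the median ratio of new to old log2 fold change was 0.916 (range 0.496 to 1.28). With the choroid covariate on all 24 libraries it was 0.952 (range 0.726 to 1.12). Genes near the low end may owe a part of their change to the 4 libraries. All 55 kept their direction and an unadjusted p under 0.05. They had been picked in a fit that holds the same libraries, so this carries little weight. No gene passed in either fit (smallest adjusted p 0.0890 and 0.0852), with a median size of 0.51 and 0.53 against 0.54 and a median SE of 0.12 in both against 0.11; why the SE rose was not tested. Dissection of CA fields against the granule layer is argued against by a median ratio of 0.967 (range 0.852 to 1.08) with the tissue covariate. All 55 were among 221 called genes there, but they had been picked on the same libraries. Fewer granule cells cannot be judged by that fit, since its covariate is a difference of 2 scores. In sedentary mice both were lower with the drug than in controls (granule 5.91 against 6.22, CA 4.61 against 4.93), so they nearly cancelled. In running mice the granule score was lower (5.97 against 6.34) and the CA score higher (5.31 against 4.92). The granule list had a median of -0.11 (20 members, SD 0.58, and Prox1, chosen after its values were seen, at 0.0073). That lay 1.07 above Calb1 and 0.56 above its 95% interval (-1.69 to -0.67). Calb1 is the member with the smallest p, so the gap was nearly fixed in advance and decides nothing. A bound of 1 SD above that interval, also tried, was missed. Tdo2 was at -1.92 and Dsp at -1.66, and an effect of the drug stays open.

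Single libraries far from the rest of their group were found in 8 of 80 groups over 16 measures. The rule is nominally set at about 1 in 20 by chance, but its rate was not tested here. The measures also overlap, as Ttr and the choroid plexus score flagged the same library. In the combined group these were Ttr at 296.6 CPM in replicate 5 (nearest 3.39), App at 3340.0 CPM in replicate 2 (nearest 3878), Penk at 212.9 CPM in replicate 3 (nearest 78.8), Rn45s at 0.817% of counts in replicate 2 (nearest 1.35%) and the choroid plexus score at 2.37 in replicate 5 (nearest -0.48). Grm2 was at 100.3 CPM in drug replicate 2 (nearest 81.8). In WT, Rn45s took 2.78% of counts in replicate 2 (nearest 1.504%) and the ribosomal protein score was 7.53 in replicate 3 (nearest 7.32).

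The drug effect differed between running and sedentary mice for 12 lists at the preset correlation, and for none with an estimated one. The difference was negative for astrocyte genes (adjusted p = 0.0196, and 0.604 with an estimated correlation), oligodendrocyte genes (adjusted p = 0.0287, and 0.723 with an estimated correlation), endothelial genes (adjusted p = 6.34e-09, and 0.185 with an estimated correlation) and mural cell and fibroblast genes (adjusted p = 3.75e-09, and 0.185 with an estimated correlation). It was also negative for respiratory chain genes (adjusted p = 0.0163, and 0.731 with an estimated correlation), ribosomal protein genes (adjusted p = 1.05e-05, and 0.656 with an estimated correlation) and glucocorticoid and clock genes (adjusted p = 0.00744, and 0.244 with an estimated correlation). It was positive for choroid plexus genes (adjusted p = 1.25e-15, and 0.185 with an estimated correlation), pyramidal neuron genes (adjusted p = 4.42e-07, and 0.185 with an estimated correlation) and ionotropic receptor and postsynaptic genes (adjusted p = 1.05e-05, and 0.265 with an estimated correlation). The same held for synaptic vesicle genes (adjusted p = 0.000389, and 0.265 with an estimated correlation) and heat shock genes (adjusted p = 0.00282, and 0.604 with an estimated correlation). Without the 4 choroid plexus libraries the oligodendrocyte list turned direction (0.969), and the astrocyte (0.521), choroid plexus (0.783) and respiratory chain (0.913) lists lost their calls. The choroid covariate is the score of the choroid plexus list itself, so the loss of that list's call with it (0.510) says little. With this covariate the respiratory chain list turned (0.955), and the astrocyte (0.0886), oligodendrocyte (0.351) and glucocorticoid (0.0692) lists were not called. Nor were the astrocyte (0.790), heat shock (0.0531) and glucocorticoid (0.0640) lists with the midbrain covariate, or the heat shock list with the tissue covariate (0.0640). Leaving out 1 library ended the astrocyte call for APP/PS1 control replicates 4 (0.0667) and 5 (0.0606), drug replicate 4 (0.0821), exercise replicates 3 (0.0695) and 4 (0.101) and combined replicate 4 (0.0831). It ended the oligodendrocyte call for APP/PS1 control replicates 2 (0.178) and 5 (0.144), drug replicates 3 (0.0548) and 4 (0.0600), exercise replicates 4 (0.0641) and 5 (0.111) and combined replicates 1 (0.508), 2 (0.0665) and 3 (0.143). The respiratory chain call ended without APP/PS1 control replicate 4 (0.138), drug replicate 3 (0.0649), exercise replicates 1 (0.152), 2 (0.105) and 5 (0.173) and combined replicate 3 (0.333), and the heat shock call without APP/PS1 control replicate 1 (0.0604).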

How the results depend on the processing

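The fits without the 4 choroid plexus libraries and with the choroid plexus and dorsal midbrain covariates were chosen after seeing the data, and the others were planned. The 9 gene counts stayed within 1.5 times with DESeq size factors and with no filter. Where a value below differs, the cause was not tested. DESeq2 called 14 genes for the genotype, 170.0 for the drug, 61 for the wheel, 82 for both, 364 for the drug added to the wheel, 256 for the wheel added to the drug, 77 for the interaction, 608 for the drug averaged and 7 for the wheel averaged. Voom called 425, 0, 989, 876, 2162 and 1 for the drug, the wheel, the drug added, the wheel added, the drug averaged and the wheel averaged. With the compared libraries alone the genotype had 1, the drug 9, the wheel 0, the wheel added 111 and the drug averaged 17. The replicate number as a block gave 0 for the wheel and 1 for both treatments. A surrogate variable gave 0 for the wheel, 35 for the drug added and 452 for the drug averaged. The tissue covariate gave 1 for the drug added and 221 for the drug averaged, the strict filter gave 96 and the midbrain covariate 108 for the drug averaged. Without the 4 libraries, and with the choroid covariate, the wheel and the drug averaged each had 0. Leaving out 1 library gave 2 to 3 genes for the genotype, 0 to 12 for the drug, 0 to 27 for the wheel, 0 to 17 for both, 0 to 400.0 for the drug added, 0 to 2 for the wheel added, 0 to 0 for the interaction, 0 to 883 for the drug averaged and 0 to 1 for the wheel averaged. Of 126 list calls over 12 contrasts, 4 held with an estimated correlation and 7 with fry, and leaving out 1 library gave 115 to 138. Without the 4 libraries these turned direction: Aqp1 in the genotype (-0.20), Grm3 in the drug (-0.18), combined (-0.41), interaction (0.14) and drug averaged (-0.11) contrasts, and Grm2 in the combined (0.15), wheel added (0.18) and interaction (-0.22) contrasts. So did the astrocyte (adjusted p = 0.385) and choroid (0.0399) lists for the genotype, the mural list for the drug (0.725) and the wheel (0.676), the plaque-induced list for the wheel (0.590), the oligodendrocyte list for the interaction (0.969) and the granule list for the drug averaged (0.397). With the choroid covariate Grm3 turned for the drug (-0.035), both (-0.18), the drug added (0.035), the interaction (0.070) and the drug against WT (-0.038), and Grm2 for the interaction (-0.020). The respiratory list turned for the interaction (0.955), and the choroid list for the wheel averaged (0.814), the drug against WT (0.902) and the wheel against WT (0.913). The turns of the choroid list say little, since the covariate is its own score. With the midbrain covariate Grm3 turned for both (-0.011), Grm2 for the wheel added (0.17) and the astrocyte list for the wheel added (0.947). With the tissue covariate Grm3 turned for both (-0.10), Grm2 for the wheel added (0.25) and the granule list, whose score is in that covariate, for the drug averaged (0.768). A surrogate variable turned Grm3 for the drug added (0.054) and the drug against WT (-0.020), and Grm2 for the interaction (-0.34). Voom turned Grm2 for the interaction (-0.024). The strict filter turned Grm3 for both (-0.0028), and the compared libraries alone Grm2 for the wheel added (0.00094). Over single libraries left out Grm2 ranged from -0.20 to 0.19 for the wheel added and -0.15 to 0.24 for the interaction, and Grm3 from -0.10 to 0.24 for both and -0.12 to 0.051 for the drug added. The adjusted p of the thalamus and cortex list for the genotype ranged from 0.000262 to 0.694. None of these gene values passed the test. With the strict filter the split covariance of genotype and treatment was -0.000197 for the drug (against -0.0110), -0.00342 for both (against -0.0104) and 0.0064 for the wheel (against -0.00316). The sex covariate and the relation over called genes were not run.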

Other observations

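The test of granule cell overactivity was chosen after the results were seen, while the lists of neurogenesis and pyramidal neuron genes were planned.

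Genes of neuroblasts and immature neurons were higher in APP/PS1 controls than in WT in 17 of 22 cases, by a median log2 fold change of 0.12, with the peptide gene Tac2 at 3.01 (SE 0.73) and Cd24a at 0.87 (SE 0.30). The list had an adjusted p of 0.00744, or 0.255 with an estimated correlation, and at the preset one it was not called without WT replicate 3 (0.160) or the 4 high-Ttr libraries (0.290). Stem and progenitor genes were higher in 14 of 20 cases (adjusted p = 0.0674, and 0.255 with an estimated correlation). With the combined treatment 13 of 22 neuroblast genes were lower than in APP/PS1 controls (adjusted p = 0.185, and 0.641 with an estimated correlation). With the wheel added to the drug 16 of 22 were lower, by a median of -0.37, with Neurod2 at 0.91 (SE 0.27), Dpysl5 at -0.52 (SE 0.18), Ncam1 at -0.21 (SE 0.08) and the immature neuron marker Dcx at -0.49 (SE 0.21). That list had an adjusted p of 0.0439, or 0.533 with an estimated correlation, and at the preset one it was not called without drug replicates 2 (0.0550) and 4 (0.108) or combined replicates 4 (0.0998) and 5 (0.121).

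Genes of CA1 to CA3 pyramidal neurons were lower with the drug in 17 of 23 cases, by a median of -0.47, with Tspan18 at -1.76 (SE 0.47) and Hs3st4 at -0.93 (SE 0.35). The list had an adjusted p of 0.00666, or 0.887 with an estimated correlation. At the preset one it was not called without APP/PS1 control replicate 5 (0.0788), without the 4 high-Ttr libraries (0.0780), with the choroid plexus covariate (0.198) or with the midbrain covariate (0.223).

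The rise of Penk and fall of Calb1 with the drug prompted a hypothesis, that granule cells may be overactive under the drug. It needs Npy, Bdnf, Nptx2, Inhba, Vgf, Scg2, Fosb and Tac1 to be higher and Ntf3 and Fos lower on balance, and fry gave a directional p of 0.00492 for these 10 genes in the drug averaged over the wheel. The direction held for 9 of them, with Npy at 0.84, Bdnf at 0.64 and Ntf3 at -1.65, and failed for Tac1 at -0.61, and 0 passed singly. Ntf3 had already been seen among genes lowered with the drug, and a test without it, added after the first p, gave 0.0208 for 9 genes. Without Ntf3 the p was 0.116 for the drug alone and 0.0655 for the drug added to the wheel, so neither passed. Leaving out 1 library gave 0.000458 to 0.0145 with Ntf3, and without the 4 high-Ttr libraries it was 0.0229. The planned list of 28 activity-dependent and neurotrophic genes, which holds Penk and all of these genes but Fos and Fosb, was not called for the drug averaged over the wheel (adjusted p = 0.124, and 0.726 with an estimated correlation) or for the drug alone (adjusted p = 0.682, and 0.928 with an estimated correlation). The genes were tested on the data that prompted the idea, and fry does not compare them with other genes.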
